A study of Micromonas commoda with 15 samples.

How the data were processed

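Messenger RNA of Micromonas commoda, a marine green picoalga, was profiled in 15 libraries from cultures of strain RCC299. Per the labels' protocols, the cultures grew in L1 medium, flasks were prepared in early exponential growth, the metals were added a day later, and cells were collected after 48 h of exposure. RNA was extracted on a Maxwell instrument, its integrity was checked on a Bioanalyzer, and poly(A)-selected libraries were sequenced on a HiSeq 3000. Per the submitters' processing notes, the reads passed through CASAVA 2.17, Trim Galore 0.4.0, STAR and RSEM 1.3.0. The version of STAR, the genome build and the annotation are not given in the sources used here.

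The deposited values are whole-number counts per gene model, 1 table for all 15 libraries, and the authors applied no visible normalization to them. The name of the deposited table calls them HTSeq counts, while the notes list RSEM, whose estimates need not be whole, so the program that counted the reads is not settled and the counts were used as deposited. The table has 10300 rows. Each of 3 identifiers stands on more than 1 row, 6 rows in all, with different values, and these rows were kept apart. A further 29 models carry a mark for a duplicate, and 27 of them lie within 10% of the total count of their partner, so reads may be shared inside these pairs. None of the 4 identifiers printed in the report carries that mark.

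Gene names could not be attached. Of the 10300 identifiers, 0 matched the locus tags, synonyms or accessions of the RefSeq table at hand, which lists 10125 genes of assembly ASM9098v2, and the files pair the identifiers with no name. The gene lists fixed before the data were examined (metal transport, photosynthesis, stress and others) and their set tests were therefore not run, and nothing is said here about pathways. The rule for printed models, also fixed beforehand, took the models with the largest changes in each direction per exposure among those with an adjusted p under 0.05, no overlap between the compared groups and a mean of at least 5 CPM (counts scaled to library size). With unnamed models the printed identifiers were limited to those 2 that rose and 2 that fell which the rule picked in the most comparisons, ties being broken by the larger change. Other models it picked are described without an identifier.

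Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr, with its minimum count of 10, kept 10012 models and removed 288, of which 16 had no reads in any library. TMM factors, which correct for composition, ran from 0.708 in control replicate 1 to 1.34 in ZnSO4 replicate 3. All 5 groups entered 1 quasi-likelihood model with group as the only term, so that the 15 libraries shared an estimate of the spread, and the common biological coefficient of variation was 17.3%. Contrasts were tested with edgeR's quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Levels are given as TMM-scaled CPM with the standard deviation (SD) over 3 libraries. Principal components were computed on log2 CPM with a prior count of 2.

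The planned contrasts were each exposure against control, each particle against the salt of its metal, both zinc against both iron exposures, and the interaction of particle form and metal. The direct comparisons of ZnO with Fe2O3 particles, of ZnSO4 with FeCl3 and of both particles with both salts were added after the data were seen, as were the gene classes that combine several contrasts and the comparison by abundance. The same steps were run on simulated counts in which only 100 models were changed 2-fold and 100 changed 1.5-fold. With the changes placed in the Fe2O3 particle group, 9979 models were tested. The steps recovered 68% and 18% of the changed models and called 5 unchanged models. With the changes placed in the ZnSO4 group, 9978 models were tested. The shares were 71% and 24%, with 2 unchanged models called. In the data these comparisons called 7132 and 5789 models. Recovery and false calls with so many changes were therefore not tested.

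Because exposures share the 3 control libraries, overlaps and correlations across models were set beside 20 simulations of unchanged groups against the same controls. Each model was drawn independently there, so variation common to many models is not covered. The controls are too few to be split, so part of any excess may come from them. Alternatives covered DESeq2 size factors, total counts only, DESeq2 1.42.0 and limma voom (limma 3.58.1) as tools, other filters on low counts, a stricter adjusted p of 0.01, a minimum log2 fold change of 1, robust dispersion, only the groups compared, the replicate number as a block, and leaving out each library. The labels number the replicates in each group 1 to 3 but give no batch, and nothing states what a number stands for. They do not say outright that replicates are separate cultures. The p-values set differences against the spread between these libraries, and cover variation between cultures only if the replicates are separate cultures.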

Results

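The series asked how a green picoalga responds at the transcript level to metal oxide nanoparticles. Cultures of Micromonas commoda stood for 48 h without an added particle or salt, with Fe2O3 particles, with ZnO particles, or with a salt of the same metal, FeCl3 or ZnSO4. Each of the 5 groups had 3 libraries. The labels give an iron concentration of 2.4 mg/L (3e-05 M Fe2O3 particles) and a zinc concentration of 0.8 mg/L (1e-05 M ZnO particles), with the salts at the equivalent metal concentration. By atomic mass these mass and molar values do not describe equal amounts of metal and come nearer to the mass of oxide that holds the molar amount, so which mass is meant is open. The doses of iron and zinc also differ, so comparisons between the metals are not matched for dose. Total counts ran from 33473041 in control replicate 3 to 48969454 in FeCl3 replicate 1. No model took more than 1.99% of a library. Of 10012 gene models tested, 8827 (88.2%) differed among the 5 groups.

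The 4 exposures lay at different distances from the control cultures. On the first principal component, which held 54.2% of the variance, controls scored -71.2 ± 9.34 (SD, n = 3), FeCl3 cultures -28.6 ± 8.11 and ZnSO4 cultures 0.784 ± 3.77. Cultures with ZnO particles scored 43.2 ± 1.87 and those with Fe2O3 particles 55.8 ± 5.66. The second component, with 23.3% of the variance, set ZnSO4 cultures, at -53.7 ± 7.28, apart from FeCl3 cultures, at 31.4 ± 14. Cultures with ZnO particles, at -3.43 ± 0.878, and with Fe2O3 particles, at 22 ± 8.96, lay between them. The groups did not overlap on the first component. On the second, control libraries ran from -10.7 to 17.6 and overlapped those of both particle groups, and FeCl3 libraries overlapped those with Fe2O3 particles.

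**Figure D1:**
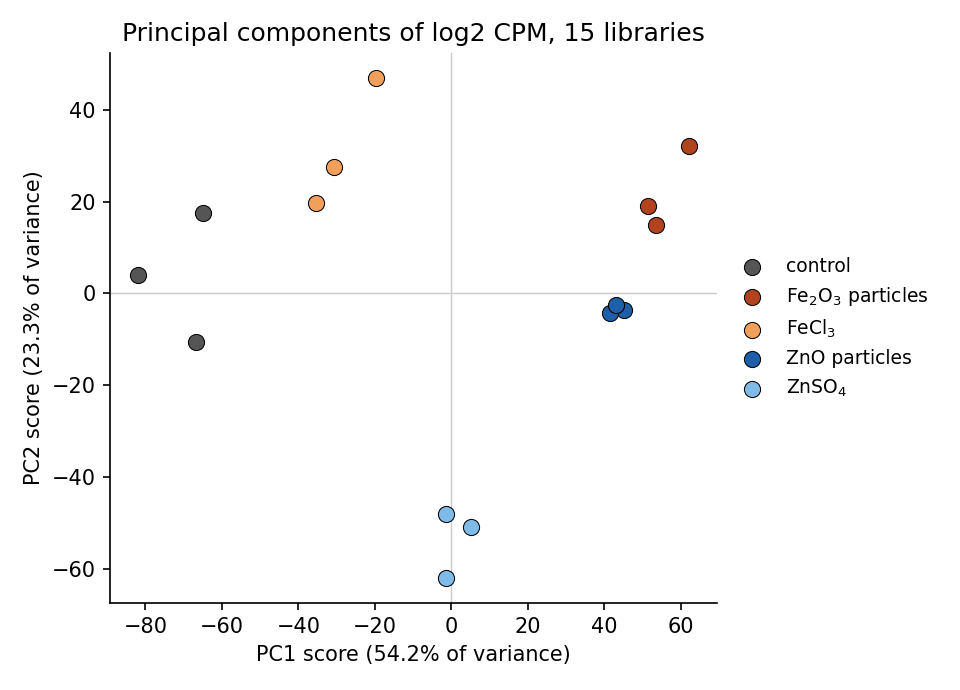
Scores of the 15 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; each point is a library, coloured by group. Controls lie at the left, both particle groups at the right, and FeCl3 and ZnSO4 cultures between them, parted along the second component.

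Fe2O3 particles changed 7132 models (71.2%), 3560 of them higher and 3572 lower than in control cultures. Of these, 2124 rose and 1822 fell at least 2-fold, and 713 rose and 509 fell at least 4-fold. Total counts as the only scaling gave 4069 higher and 2792 lower, and a mean of at least 5 CPM 3484 and 2376. Rankings of models here and in the other exposures cover called models with a mean of at least 5 CPM and no overlap with the controls. The model wlab.1800.1 rose 70.8-fold, from 0.215 ± 0.0642 CPM in controls to 15.1 ± 2.54 CPM (SD, n = 3). Its log2 fold change was 6.15 (SE 0.328), with an adjusted p of 5.88e-10 in edgeR's quasi-likelihood test, and it rested on 6 to 8 reads per control library. The model wlab.7648.1 rose 47-fold, from 4.33 ± 1.83 to 203 ± 47.2 CPM (log2 fold change 5.55, SE 0.406). In the other direction wlab.233596.1 fell from 416 ± 74.2 to 10.6 ± 0.977 CPM, a log2 fold change of -5.29 (SE 0.294), and wlab.248661.1 from 221 ± 57 to 6.66 ± 0.34 CPM, a log2 fold change of -5.05 (SE 0.287). In 3 of 3 exposed libraries these models lay outside the range of the controls, which the rule that picked them required of all but wlab.248661.1 in this comparison.

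FeCl3 at the equivalent iron concentration changed 4393 models (43.9%), 2049 higher and 2344 lower. Large changes were fewer than with the particles: 642 models rose and 593 fell at least 2-fold, and 46 rose and 39 fell at least 4-fold. The model that rose most went up 8.54-fold (log2 fold change 3.1, SE 0.317), and it also rose 11.2-fold with Fe2O3 particles, 9.4-fold with ZnO particles and 7.28-fold with ZnSO4. The models wlab.248661.1 and wlab.233596.1 fell most, to 26.2 ± 11.2 and 58 ± 26.2 CPM, with log2 fold changes of -3.07 (SE 0.26) and -2.84 (SE 0.261). The printed risers of the particle exposure changed less here. The model wlab.1800.1 reached 0.591 ± 0.147 CPM (log2 fold change 1.46, SE 0.395, adjusted p of 0.00824 in the same test; limma voom alone did not call it). The model wlab.7648.1 stood at 8 ± 3.08 CPM, and its log2 fold change of 0.88 did not pass the threshold (SE 0.359, adjusted p of 0.0571 in edgeR's quasi-likelihood test). It was called without FeCl3 replicate 1, at 1.19, without control replicate 2, at 1.07, and by DESeq2, at 0.88, and it was 0.57 without control replicate 1. Total counts only, a mean of at least 5 CPM and the replicate number as a block called it as well. With total counts as the only scaling the models changed divided into 3160 higher and 1348 lower.

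ZnO particles changed 6384 models (63.8%), 3012 higher and 3372 lower. At least 2-fold changes covered 1700 higher and 1466 lower models, and at least 4-fold changes 578 and 437. The model wlab.1800.1 again rose most, 91.2-fold to 19.5 ± 1.82 CPM (log2 fold change 6.51, SE 0.329, adjusted p of 4.65e-10 in edgeR's quasi-likelihood test), and wlab.7648.1 rose 27.2-fold to 118 ± 20.4 CPM (log2 fold change 4.76, SE 0.393). A model without a printed identifier rose more than the latter, with a log2 fold change of 5.25 against 4.51 for Fe2O3 particles. The models wlab.248661.1 and wlab.233596.1 fell most, to 7.04 ± 0.645 and 13.8 ± 0.89 CPM, with log2 fold changes of -4.97 (SE 0.286) and -4.92 (SE 0.289). Total counts as the only scaling gave 4179 higher and 1971 lower, and without any 1 library of ZnO particles the calls were 3001 to 3061 higher and 2711 to 2744 lower.

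ZnSO4 changed 5789 models (57.8%), 2221 higher and 3568 lower, and the large changes leaned the other way. At least 2-fold rises numbered 1394 and falls 681, at least 4-fold rises 559 and falls 30. The median model had a log2 fold change of -0.23, so the split is relative to that shift. Centring each exposure on its median model gave 2727 higher and 2131 lower, fitting only the groups compared gave 2435 and 1697, and total counts only gave 3709 and 734. Without any 1 of the ZnSO4 libraries the majority also turned, with 2413 to 2671 higher and 1617 to 1732 lower. The models wlab.248661.1 and wlab.233596.1 again fell most, to 17.5 ± 1.5 and 38.4 ± 4 CPM, with log2 fold changes of -3.65 (SE 0.267) and -3.44 (SE 0.268). The model wlab.1800.1 rose 19.6-fold to 4.17 ± 1.37 CPM (log2 fold change 4.29, SE 0.334), and wlab.7648.1 rose 2.12-fold to 9.16 ± 3.27 CPM (log2 fold change 1.08, SE 0.358), a call lost without control replicate 1, at 0.77. The models that rose most with ZnSO4 were others. The first, from 1.34 ± 1.99 to 31.2 ± 8.44 CPM, had a log2 fold change of 4.61 (SE 0.696). It became 7.32 without control replicate 3 and 4.02 without control replicate 2, where wlab.1800.1 was at 4.15. The second rose 20.2-fold (log2 fold change 4.34, SE 0.463). Its log2 fold change became 5.41 without control replicate 3 and 3.98 without control replicate 1. The rank of both above wlab.1800.1 thus turns on single control libraries.

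**Figure D2:**
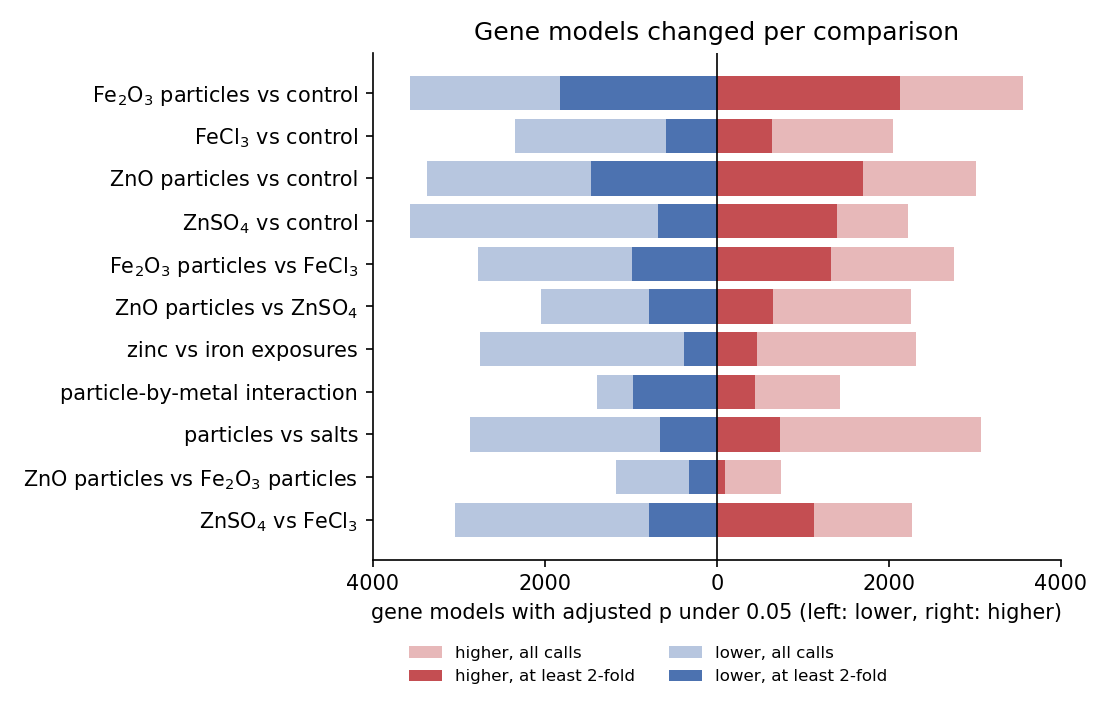
Numbers of gene models with an adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0; dark bars are those changed at least 2-fold. In the fit shown, Fe2O3 particles changed the most models against control (7132) and FeCl3 the fewest (4393). With total counts only ZnSO4 had fewer (4443) than FeCl3 (4508). With only the groups compared ZnO particles had 6164 and Fe2O3 particles 6156.

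**Figure D3:**
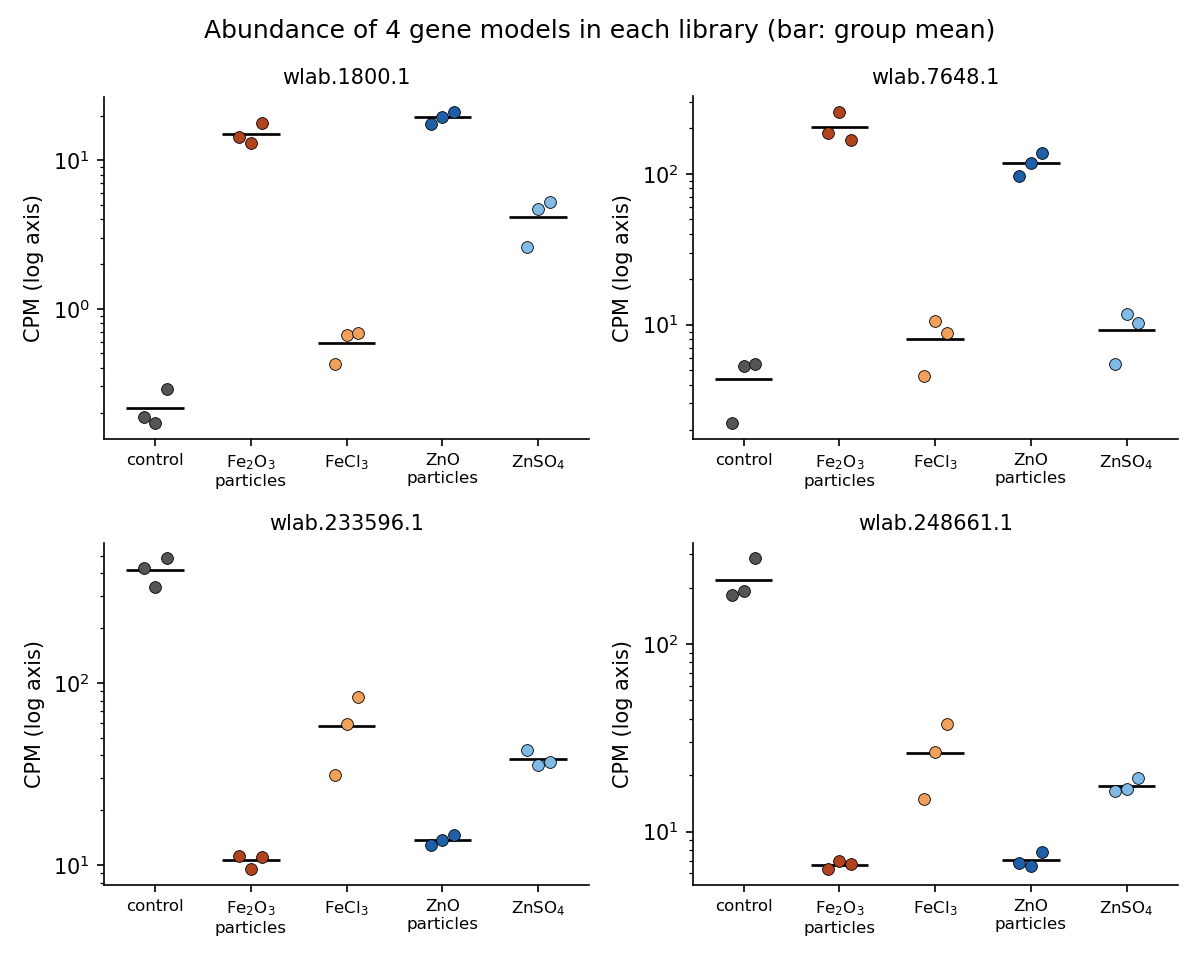
CPM of the 4 printed models in each library on log axes, by group; points are libraries and bars are group means. The models wlab.1800.1 and wlab.7648.1 are highest in both particle groups, while wlab.233596.1 and wlab.248661.1 are lowest there, at 6.66 to 13.8 CPM on average.

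Both particles changed largely the same models in the same direction. Against control, 2665 models were higher and 2970 lower in both, where independent lists would share 1071 and 1203, and 51 went in opposite directions. Across models the log2 fold changes had r = 0.935 and a covariance of 1.47, beside 0.514 and 0.03 for simulated unchanged groups that share the controls, which shared 0 calls. Genes are not independent replicates, and part of the excess may come from the shared controls. A particle and the salt of its metal shared fewer calls. For iron 1590 models were higher and 1948 lower in both (729 and 836 for independent lists), 175 were opposite, and r was 0.714 with a covariance of 0.653. For zinc 1799 were higher and 2424 lower in both (668 and 1202), 195 were opposite, and r was 0.769 with a covariance of 0.914. The simulated values were r = 0.519 and a covariance of 0.0301 for iron, and 0.519 and 0.03 for zinc. A particle and the salt of the other metal overlapped as well. Fe2O3 particles and ZnSO4 shared 1665 higher and 2310 lower models, with 577 opposite, r = 0.667 and a covariance of 0.875. ZnO particles and FeCl3 shared 1267 and 1814, with 240 opposite, r = 0.653 and a covariance of 0.541. The overlap of particle and salt is therefore not particular to the metal. Between the salts, 889 models were higher and 1566 lower in both (455 and 835 for independent lists), and 325 were higher with FeCl3 and lower with ZnSO4 against 94 the other way round. The salts had r = 0.42, below the simulated 0.521, and a covariance of 0.291, above the simulated 0.0299. Total counts as the only scaling gave shared calls of 3432 higher and 1850 lower for the particles, 2295 and 1174 for iron, and 2893 and 543 for zinc.

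**Figure D4:**
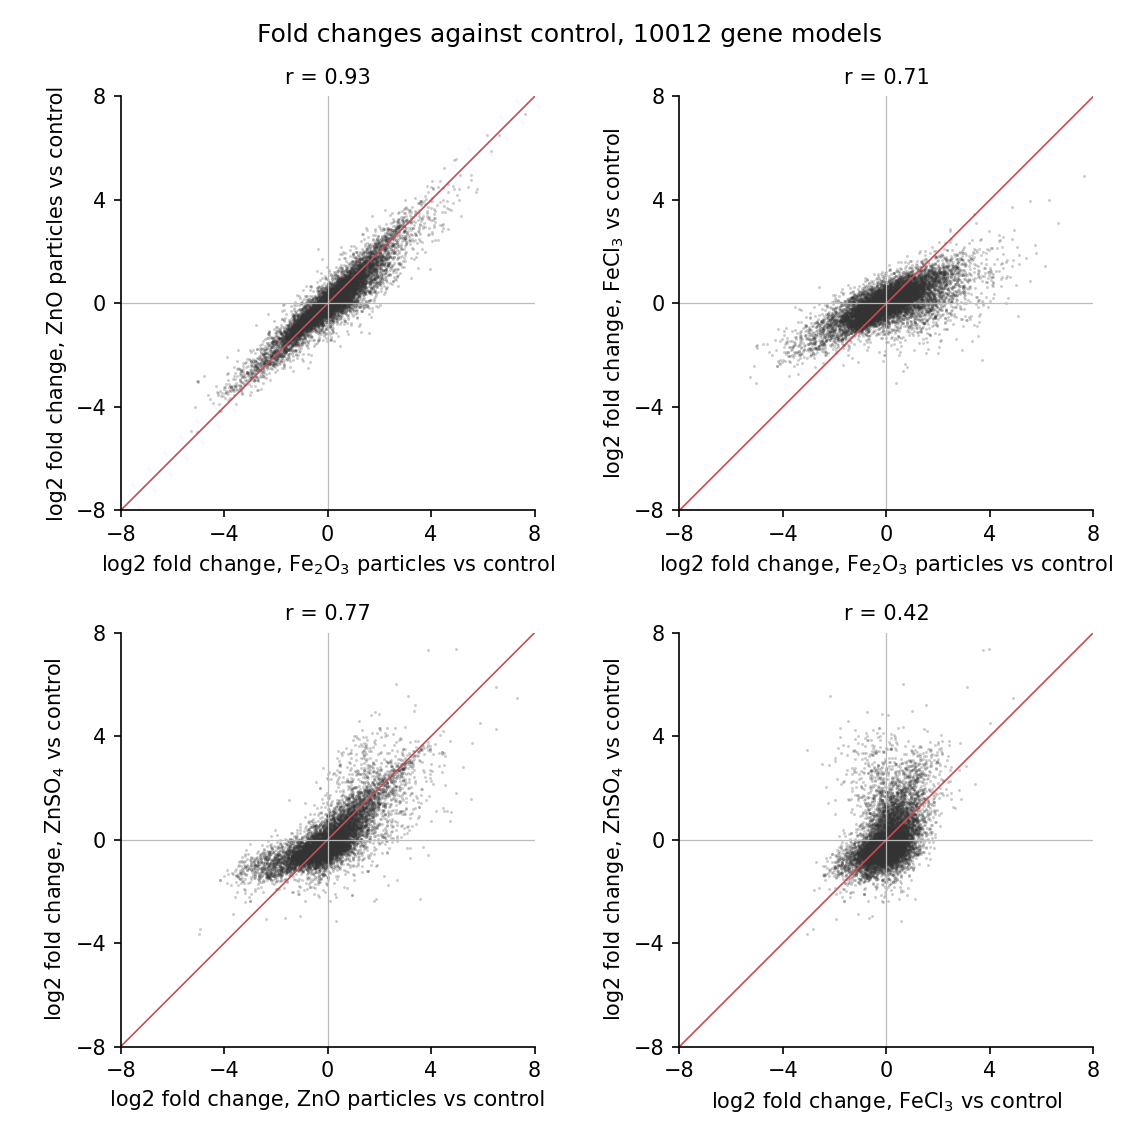
Log2 fold change against control of the 10012 tested models in pairs of exposures, each point a model and the red line equality; r is across models. The particles follow the line (r = 0.93), the salts spread around it (r = 0.42). FeCl3 reaches less far than Fe2O3 particles, with 46 models up and 39 down at least 4-fold against 713 and 509.

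Sorting the models by their calls gave groups common to the exposures and groups held by the particles. In all 4 exposures 797 models were higher, with median log2 fold changes of 1.8 for Fe2O3 particles, 1.01 for FeCl3, 1.73 for ZnO particles and 1.45 for ZnSO4. The number lower in all 4 was 1379, with medians of -1.44, -0.78, -1.25 and -0.77. This second count depends on the processing: it was 992 with each exposure centred on its median model, 648 with only the groups compared, 327 with total counts only, and between 706 and 820 without FeCl3 replicate 1 or any single library of ZnO particles or ZnSO4. The first count was 1420 with total counts only. A further group of 948 models was higher with both particles and also above both salts, with medians of 1.43 for Fe2O3 particles and 1.12 for ZnO particles against 0.31 for FeCl3 and 0.12 for ZnSO4. Of these, 344 were called in neither salt. The matching group that was lower with both particles and below both salts had 1187 models, with medians of -1.68 and -1.55 against -0.63 and -0.68, and 191 of them were called in neither salt. Both groups were picked by these same differences, so the gap between particle and salt medians follows from the rule. Among models called in the same direction in Fe2O3 particles and FeCl3, the salt's change was the smaller in 85.1%, with a median size ratio of 0.625. For ZnO particles and ZnSO4 it was the smaller in 68%, with a ratio of 0.819. Among all models higher with ZnSO4, its change was the smaller in 46.5%.

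Tested directly, Fe2O3 particles differed from FeCl3 in 5532 models, 2755 higher and 2777 lower, of which 1322 and 989 differed at least 2-fold. The model wlab.1800.1 was 25.7-fold and wlab.7648.1 25.5-fold higher with the particles (log2 fold changes 4.68, SE 0.276, and 4.67, SE 0.384), while wlab.233596.1 and wlab.248661.1 were lower, at -2.45 (SE 0.261) and -1.98 (SE 0.256). ZnO particles differed from ZnSO4 in 4308 models, 2261 higher and 2047 lower, of which 655 and 789 differed at least 2-fold and 114 and 153 at least 4-fold. The printed models differed in the same directions: wlab.1800.1 was 4.65-fold and wlab.7648.1 12.8-fold higher (log2 fold changes 2.22, SE 0.23, and 3.68, SE 0.367), and wlab.233596.1 and wlab.248661.1 were lower, at -1.48 (SE 0.253) and -1.31 (SE 0.252). They do not stand for all picked models: the 2 that rose most with ZnSO4 were 10.6-fold and 5.02-fold lower with ZnO particles. The split for zinc depends on the scaling. It was 1470 higher and 3040 lower with each exposure centred on its median model against control. Such centring moved the median log2 fold change of this contrast itself from 0.014 to -0.17. Total counts only gave 1287 and 2768. The split turned the same way whichever 1 of the 6 libraries was left out, with 1296 to 1512 higher and 2164 to 2335 lower. These iron and zinc contrasts share no library. They had 1316 models higher and 1294 lower in common (622 and 568 for independent lists) and 337 opposite. Across models r was 0.467, beside 0.00384 in a simulation that drew each model independently. Centring gave 993 and 1758 in common.

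Taken over both metals, particles differed from salts in 5936 models, 3071 higher and 2865 lower, of which 740 and 663 differed at least 2-fold. Total counts only gave 2335 higher and 3395 lower. Without Fe2O3 particles replicate 3, FeCl3 replicate 1 or any 1 zinc library it was 2529 to 2813 higher and 3000 to 3308 lower. The model wlab.7648.1 was 18.1-fold higher with particles (log2 fold change 4.17, SE 0.265), and wlab.1800.1 10.9-fold (3.45, SE 0.18).

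The zinc exposures differed from the iron exposures in 5071 models, 2314 higher and 2757 lower, but mostly by small amounts: 467 and 382 differed at least 2-fold. Most of this lay between the salts. ZnSO4 differed from FeCl3 in 5314 models, 2268 higher and 3046 lower, with 1127 and 794 at least 2-fold. ZnO particles differed from Fe2O3 particles in 1922 models, 750 higher and 1172 lower, with 98 and 321 at least 2-fold. Of the printed models 1 was called between the salts and none between the particles. The model wlab.1800.1 was 7.12-fold higher with ZnSO4 than with FeCl3 (log2 fold change 2.83, SE 0.27), and between the particles its log2 fold change was 0.37 (SE 0.218, adjusted p of 0.269 in edgeR's quasi-likelihood test). The model wlab.7648.1 had log2 fold changes of 0.20 between the salts and -0.79 between the particles, with adjusted p of 0.639 and 0.109 in the same test. The 2 models that rose most with ZnSO4 were 68.7-fold and 24.9-fold higher there than with FeCl3. The directions depend on the scaling. For zinc against iron and for the salts they also turned when any 1 of several libraries was left out. The median log2 fold change of zinc against iron then moved alike, from -0.019 to 0.109 without Fe2O3 particles replicate 3 and to 0.104 without FeCl3 replicate 1. Centring each exposure on its median model against control gave 3376 higher and 1903 lower for zinc against iron. It gave 3329 and 1865 for the salts, and 971 and 1009 for the particles. The median log2 fold changes of these contrasts were then 0.12, 0.14 and 0.06, so the contrasts themselves were not centred. Total counts only gave 3918 and 1310, 3436 and 1434, and 1795 and 593. Without Fe2O3 particles replicate 3, FeCl3 replicate 1 or any 1 zinc library, zinc against iron had 2890 to 3075 higher and 1712 to 1943 lower. Without FeCl3 replicate 1 or any 1 ZnSO4 library the salts had 2574 to 2753 and 1603 to 1899. The count for the particles was 1044 without ZnO particles replicate 2.

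The difference between particle and salt was itself different in zinc and iron for 2829 models, 1437 with a higher and 1392 with a lower value in zinc, of which 439 and 972 differed at least 2-fold. Among them 1978 (69.9%) had the larger difference in iron, and 337 were called in opposite directions, 231 of these being higher with Fe2O3 particles than with FeCl3 and lower with ZnO particles than with ZnSO4. The model wlab.1800.1 was among the 2829, with an interaction of -2.47 (SE 0.347, adjusted p of 0.000137 in edgeR's quasi-likelihood test), and wlab.7648.1 was not, at -0.99 (SE 0.473, adjusted p of 0.134 in the same test). It was called without ZnSO4 replicate 1, at -1.4, and with the replicate number as a block, at -1.0. The split was 784 higher and 1825 lower with each exposure centred, where the median interaction moved from 0.085 to -0.10. With only the groups compared the split was 1209 and 1800, and with total counts only 818 and 1438. Without any 1 of the 12 exposed libraries it was 681 to 1339 higher and 1196 to 1817 lower, with lower values in the majority each time.

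In each exposure scarce models rose relative to abundant models. Whether a bin lies above or below 0 depends on the scaling. With total counts only the median model stood at 0.25 for Fe2O3 particles, 0.29 for FeCl3, 0.34 for ZnO particles and 0.31 for ZnSO4. With TMM it stood at 0.02, 0.01, -0.04 and -0.23, and the bins below are on that scaling. Models were divided into 5 equal bins by mean abundance over all libraries. With Fe2O3 particles the median log2 fold change went from 0.57 in the lowest bin to -0.41 in the highest, where 25.6% of models were higher and 50.4% lower. With ZnO particles it went from 0.51 to -0.44, with FeCl3 from 0.26 to -0.34, and with ZnSO4 from 0.37 to -0.54. The interquartile range of log2 CPM within a library averaged 3.88 ± 0.227 in controls (n = 3). It was 3.54 ± 0.18 with Fe2O3 particles, 3.52 ± 0.0194 with FeCl3, 3.41 ± 0.0115 with ZnO particles and 3.21 ± 0.17 with ZnSO4 (n = 3 each). A two-sided exact permutation test of the 12 exposed against the 3 control libraries gave p = 0.0044. That test takes all libraries as interchangeable, although they come in groups of 3 with levels of their own. Its p can therefore be too small. Taken alone, Fe2O3 particles gave an exact p of 0.2 and each of the other exposures 0.1, the smallest that 3 against 3 allow, with adjusted values of 0.2 and 0.133 over the 4.

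**Figure D5:**
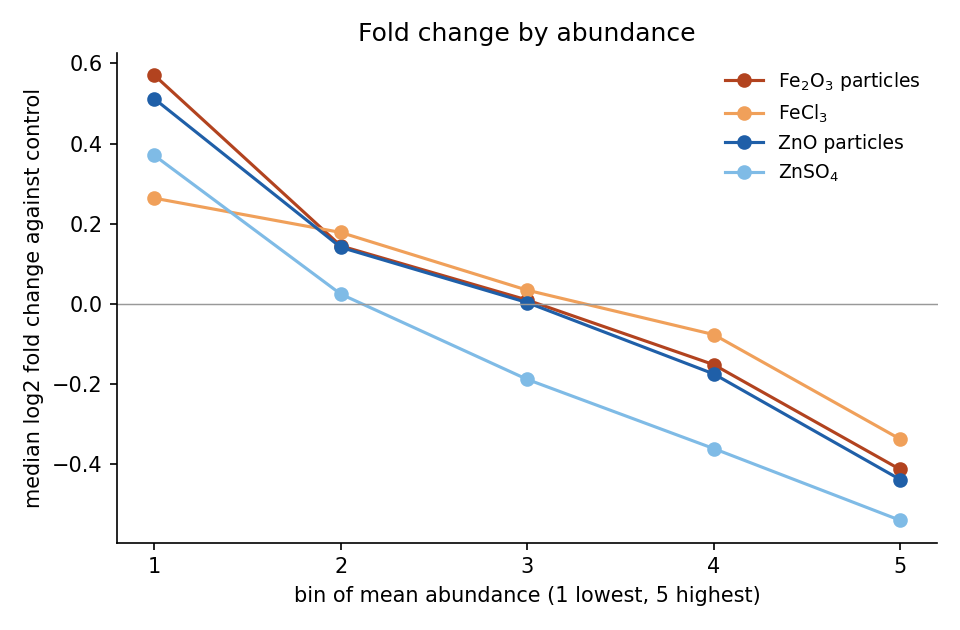
Median log2 fold change against control by bin of mean abundance, from lowest (1) to highest (5), for the 4 exposures. With TMM scaling each line falls from above 0 (0.26 to 0.57) to below 0 (-0.34 to -0.54). The position of 0 depends on the scaling.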

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

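The tests on shared control libraries and on background reads, and the direct comparisons of the particles, of the salts and of particles with salts, were chosen after the results were seen.

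The particle-versus-salt difference was not the same for zinc and iron in 2829 models, by a test of the interaction itself. It was called in iron alone for 1383 of them, in zinc alone for 567, in both with the same direction for 498, in both with opposite directions for 337 and in neither for 44. Among the printed models wlab.1800.1 had an interaction of -2.47 (SE 0.347, adjusted p of 0.000137 in edgeR's quasi-likelihood test). It stood 4.65-fold over the salt with ZnO particles and 25.7-fold with Fe2O3 particles. Against control ZnO particles raised it 91.2-fold, Fe2O3 particles 70.8-fold, ZnSO4 19.6-fold and FeCl3 2.76-fold. It was called between the salts and not between the particles. The model that rose most with ZnSO4 had an interaction of -4.97 (SE 0.98, adjusted p of 0.00178 in the same test), and the second of those -4.17 (SE 0.599, adjusted p of 0.000163 in the same test).

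Both particles moved largely the same models. Shared control libraries do not enter Fe2O3 particles minus FeCl3 and ZnO particles minus ZnSO4, which share no library and still had r = 0.467 across models. They cannot be the cause of that value. Simulated unchanged groups reached at most 0.0348, but each model was drawn independently there. The simulation therefore cannot show what r variation common to many models would give. After the trend with abundance was removed, the particles against control had r = 0.93. These 2 contrasts share the controls, which gave r = 0.514 for simulated unchanged groups, without a trend removed. For the differences from the salts, in which that trend partly cancels, r was 0.48. These values argue against a shift that depends on abundance alone, as far as the shared controls and the partial cancelling allow. A candidate explanation is a response to the particle form that does not depend on the metal. It is a hypothesis found on these cultures and was not tested. It may cover only part of the response, since the particles themselves differed in 1922 models, though at doses that were not matched. The particle-versus-salt difference differed between the metals in 2829 models, but this can come from the salts, which differed in 5314 models. Joint handling of the particle cultures apart from the salt cultures stays untested, because the labels give no batch.

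The exposed cultures had on average a narrower range of abundance than the controls, by -0.46 in the interquartile range of log2 CPM. The libraries overlapped slightly. Control replicates 1, 2 and 3 stood at 4.12, 3.668 and 3.857, and the highest exposed library, Fe2O3 particles replicate 2, at 3.67. The mean difference stayed at -0.46 after all libraries were thinned to the smallest total, which argues against depth. It was also -0.46 without the 100 most abundant models. The measure is a ratio of quartiles within a library, which does not move with scaling. Leaving out so few models had to leave it nearly unchanged, so this is no test of a few models taking most counts. Background reads added to every model would leave abundant models alike, yet the most abundant bin fell below the middle bin in each exposure, by -0.35 for ZnSO4 and by -0.37 to -0.44 for the others. For scarce models such a background cannot be told apart from a rise in their transcripts. A constant background set from the rise of the 1st percentile of levels over control gave 0.171 of the observed 0.57 for Fe2O3 particles. Another level, or a background that follows gene length, may give more, and lengths could not be joined to the models. A change in the cells under metal exposure, or in how the control cultures were handled, stays open and untested.

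Other divisions of the same libraries were run as a guard against chance. In each of the 8 comparisons of 3 libraries against 3, 1 of 10 splits, the real one, gave as many models, which is too few splits for a share under 0.05. The real splits, fitted alone with edgeR, gave 6156 models for Fe2O3 particles, 2977 for FeCl3, 6164 for ZnO particles and 4132 for ZnSO4 against control. They gave 4915 for Fe2O3 particles against FeCl3, 5634 for ZnO particles against ZnSO4, 2086 between the particles and 5311 between the salts, and the highest other split gave 0 in each. For the larger comparisons 1 of 100 drawn splits, the real one, gave as many models, a share under 0.05. Chance is excluded there only as far as the libraries are not interchangeable: drawn splits put exposures that differ into the same group, so their low counts do not single out the contrast named. These fits held only the 2 sides of a split as groups for zinc against iron and for particles against salts, so their real counts are below the reported 5071 and 5936. The real and the highest other counts were 1939 and 373 for zinc against iron, 3906 and 2109 for particles against salts, 3009 and 1937 for the interaction, and 8827 and 4603 for any difference among the 5 groups. Zinc against iron and particles against salts divide the same 12 libraries, and the second division, not among those drawn for the first, gave more models than the first.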

How the results depend on the processing

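Centring on the median model, leaving out duplicate-marked models, and all alternatives for the added comparisons, shared calls of the particles and of particle minus salt, model classes and the trend with abundance were chosen after seeing the data. No log2 fold change of a picked model that passed the threshold changed sign, but the majority direction of the calls did turn. It turned with total counts only in every comparison except Fe2O3 particles against FeCl3, and in both classes over all 4 exposures the balance turned too (1420 higher and 327 lower). Of the counts of models changed, 237 stayed within 1.5 times the reported value and 16 did not. A mean of at least 5 CPM gave 3712 models for ZnSO4 against control, 2094 higher and 1618 lower, with the median log2 fold change at -0.02 in place of -0.23, and turned the majority to higher for the other 3 exposures (2615 and 1516 for FeCl3), for the 3 sets of shared calls against control and for Fe2O3 particles against FeCl3, and to lower for the interaction. An adjusted p of 0.01 gave 2678 for FeCl3 against control, 1573 for the interaction, 963 between the particles, and 2256 shared calls for iron and 1712 for particle minus salt. A log2 fold change of at least 1 gave 3946 for Fe2O3 particles, 1235 for FeCl3, 3166 for ZnO particles and 2075 for ZnSO4 against control. It gave 2311 for Fe2O3 particles against FeCl3, 1444 for ZnO particles against ZnSO4, 849 for zinc against iron, 1411 for the interaction, 1403 for particles against salts, 419 between the particles and 1921 between the salts. Shared calls were then 1523 for zinc, 1040 for iron, 2783 for the particles and 687 for particle minus salt. The falls at an adjusted p of 0.01 and a log2 fold change of at least 1 come from the stricter rule. Leaving out 1 library gave 1044 to 1672 between the particles (lowest without ZnO particles replicate 2), 6583 to 7074 for Fe2O3 particles, 2961 to 5040 for FeCl3, 5712 to 6419 for ZnO particles and 4087 to 5704 for ZnSO4 against control. With DESeq2 size factors the majority turned for Fe2O3 particles against control (3641 higher and 3464 lower) and against FeCl3 (2886 and 2632). It also turned for ZnO particles against ZnSO4 (2118 and 2212), zinc against iron (2604 and 2494) and the interaction (1167 and 1511). Shared calls turned too, to 2095 higher and 1596 lower for zinc with centring, and to 799 and 1700 for particle minus salt with total counts only. Not every split that moved is given, and the cause was not tested.

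Of the log2 fold changes of the models picked by the naming rule, 1454 stayed on the same side of the threshold, called or not, 21 passed it newly and 5 no longer did. For wlab.7648.1 with FeCl3 it was gained with DESeq2 at 0.88, total counts at 1.1 and a mean of at least 5 CPM at 1.05. With the replicate block the same call was gained at 0.89, as was its interaction, at -1.0, while the counts moved by less than 1.5 times (7176 for Fe2O3 particles, 4427 for FeCl3, 6443 for ZnO particles and 5858 for ZnSO4 against control). The replicate numbers were not taken to pair samples in the reported fit, because the labels do not say what a number stands for. The values show some likeness by number. Of 30 pairs with the same number, with residual r from -0.457 to 0.684, 17 were over 0.1. In addition, 11 of 15 libraries were closest to their own number. A structure by replicate is therefore not excluded, and the reported fit leaves it out. The fall from scarce to abundant models moved by more than its spread in 7 values and by less in 61, with its direction kept. Alternatives without organelle, rRNA or over 5% genes were not run, as no model could be named and none passed 5%, nor were the gene list tests. Depth limits the scarcest models: wlab.1800.1 had 6 to 8 reads in each control library.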

Other observations

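The models that differ between the metals as particles may be those that differ between the metals as salts. This was put as a test before its result was seen: ZnO minus Fe2O3 particles and ZnSO4 minus FeCl3 share no library, so unrelated differences would give r near 0 across models. The value was 0.341, with the caveat that genes are not independent replicates. Of the 1922 models that differed between the particles, 1315 also differed between the salts, 1118 of these in the same direction and 197 in the opposite one. Higher with zinc in both were 271 and lower in both 847, where independent lists would share 170 and 357. These directions are relative to the scaling, and the metals were given at different doses, so metal and dose are confounded.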
